A study of Mus musculus with 17 samples.

How the data were processed

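RNA-seq was made from sorted spleen B cells of WT and DKO mice, per the labels with SMART-Seq v3 ultra low input amplification of polyA RNA and Nextera libraries. ATAC-seq was made from the same sorted populations. Per the labels, FoB WT (n = 2), FoB DKO (n = 3) and ABC DKO (n = 3) RNA libraries form a first table, 4 additional libraries of ABC WT (n = 2) and ABC DKO (n = 2) a separate one, and FoB DKO (n = 2), ABC DKO (n = 2) and ABC WT (n = 1) ATAC libraries the peak lists. Groups were taken from the labels and the replicate numbers.

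The deposited RNA tables hold, per sample, log2 CPM values that the authors made with edgeR after quality checks with FastQC, for 11561 genes in the first table and 9684 in the other, with the mm10 gene coordinates and exon lengths, after a filter on genes that the sources used here do not state. The authors' tables also give a log2 fold change, a likelihood ratio statistic, a p-value and an FDR from their own edgeR model, used here only for a count of their calls. In the first table unquoted commas had shifted the cells of 2681 lines, which were rejoined before reading. The aligner and the counting tool are not given in the sources used here. The peak lists were made by the authors with HOMER 4.7.2 (findPeaks in its factor style, mm10), once for each library. In the deposited DKO lists the score is a constant and only coordinates differ, and the order of lines is not documented. The ABC WT list gives, per the file headers, the signal as normalized tag counts, a focus ratio, which is a fraction, a findPeaks score, the fold ratio over the local region, and a Poisson p-value for it. Fragment lengths set by the authors' peak calling were, per the file headers, 56 bp in FoB DKO and ABC WT and 162 bp in ABC DKO.

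Because log2 CPM moves in steps of 1 read, each library's size was recovered from the steps of its lowest values. Within a tolerance of 0.1 read, 100.0% of values up to 100 reads were whole in every library. Recovered sizes ran from 14.25 to 23.65 M reads in the first table and from 28.33 to 31.51 M in the other. The lowest value, a count of 0 with the authors' prior count of about 1 read, was -4.31 and -4.89 in these tables, so fold changes against a group near it depend on that prior. ATAC libraries held 156.3 and 163.7 M tags (FoB DKO), 163.1 and 162.2 M (ABC DKO) and 126.8 M (ABC WT), with 11.5%, 12.3%, 17.1%, 16.4% and 15.4% of tags in peaks.

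The design, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The design assumed counts, but the values are log2 CPM, so limma 3.58.1 in R 4.3.3 was used with a trend of variance on mean level and moderated statistics, with a group term and no block. The first table was fitted with all 8 libraries and the other with its 4. Genes with more than 1 CPM in at least 2 libraries were tested, which removed 21 genes from the first table and 0 from the other. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05. Of the 32 fixed lists, the sort markers and the deleted genes were read gene by gene and not tested as lists. The remaining lists with at least 5 tested members were compared with the other genes by camera. The preset correlation was 0.01, and p-values were adjusted over the lists of a comparison. Members were also adjusted over the list alone. The named genes are Def6, Swap70 and the genes of the sort markers, then the 10 largest positive and 10 largest negative log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and every library of 1 group above the other's, with immunoglobulin and T cell receptor segments, unnamed gene models, small RNAs and mitochondrial transcripts left out, and up to 4 members of each list with the smallest p-values, called or not.

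Replicate numbers were checked for pairing by correlating deviations from the group means across genes. FoB DKO and ABC DKO libraries of the same number gave r = 0.709, 0.614 and 0.362, so values with the number as a block are given beside that comparison. Other pairs of these groups gave negative values, which follow in part from the positive ones because deviations within a group cancel. On simulated data with known changes the fit recovered 13.4% of 2-fold and 54.5% of 4-fold changes for FoB DKO against FoB WT, 32.8% and 60.6% for ABC DKO against FoB DKO, and 47.8% and 95.5% for ABC DKO against ABC WT, with 3 of 48, 3 of 67 and 9 of 110 calls false. Only 67 genes were changed by 2-fold and 66 by 4-fold, far fewer than were called in the data, so these shares need not hold there.

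Peaks were compared with bedtools 2.31.1 at a minimum overlap of 1 bp. A peak was taken as replicated when found in both lists of a group, and as ABC-only or FoB-only when it overlapped neither list of the other cell type. Shares carry 95% Clopper-Pearson intervals, which hold counting error only. Genes with such a peak within the gene or 20 kb of it were compared by Fisher's exact test, 2-sided, over genes. This took the peak coordinates as mm10, as labelled, without a separate check of the build. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

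Alternatives were quantile normalization, no filter, a filter at 5 CPM, a prior count 10 times larger or at 0.1 of its size, immunoglobulin genes left out, fits with only the groups compared, a block by replicate number, a log2 fold change of at least 1, leaving out each library, an estimated correlation, fry, a 50% reciprocal overlap, the first part of each list and lists of 114220 peaks each, both by line order in the DKO lists, where it is not documented as a strength, and by tag count in ABC WT, and distances of 5 and 100 kb. Chosen after the data were examined were limma-voom on recovered reads, removal of the exon length trend, centring on the median gene, windows of 200 bp around peak centres and combinations of these. The difference between the genotype effects in FoB and ABC was not tested, because the design fixed a test only for tables of counts, so the effects were set side by side. Motif content, and exon or intron position of peaks, were not analysed here, as no genome sequence or transcript models were used.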

Results

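Transcripts and open chromatin were measured in B cells sorted from the spleens of female mice older than 20 weeks, either C57BL/6 wild type (WT) or lacking both Def6 and Swap70 (DKO), the genes of the SWEF proteins. Follicular B cells (FoB), the resting recirculating B cells, were sorted as B220+CD19+CD23+CD11c-CD11b-. Age-associated B cells (ABC), a CD11c-positive memory-like population that expands with age and in autoimmunity, were sorted as B220+CD19+CD11c+CD11b+. RNA-seq covered FoB WT (n = 2), FoB DKO (n = 3) and ABC DKO (n = 3) in a first table, and additional libraries of ABC WT (n = 2) and ABC DKO (n = 2) in a separate table. ATAC-seq peak lists covered FoB DKO (n = 2), ABC DKO (n = 2) and ABC WT (n = 1). Reads recovered from the steps of the deposited values came to 19.4 and 19.5 M reads for the FoB WT libraries, 14.7, 23.1 and 22.6 M for FoB DKO, and 14.3, 23.7 and 22.1 M for ABC DKO. The additional libraries held 28.6 and 29.6 M reads for ABC WT and 28.3 and 31.5 M for ABC DKO. The labels do not state whether libraries came from separate animals, so each p-value measures the spread between samples.

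Def6 and Swap70, which encode regulators of Rho GTPases that also bind interferon regulatory factors, came first. Def6 stood at 7.45 and 7.36 log2 CPM (read counts scaled to library size) in the FoB WT libraries, and at 2.16, 2.54 and 0.88 in FoB DKO. ABC DKO held 2.06, 1.86 and 1.66. In the additional libraries Def6 was 6.48 and 6.22 in ABC WT and 3.06 and 2.95 in ABC DKO. Swap70 stood at 9.75 and 9.77 in FoB WT, at 8.08, 7.88 and 8.03 in FoB DKO, and at 7.76, 8.12 and 8.05 in ABC DKO. The additional libraries gave 9.31 and 9.24 for Swap70 in ABC WT, and 7.57 and 8.03 in ABC DKO. The values count reads over the whole gene, so reads outside a deleted part still count. Against WT, Def6 changed by -5.54 (SE 0.44) on the log2 scale in FoB DKO (limma adjusted p = 9.9e-04) and by -3.35 (SE 0.13) in ABC DKO (adjusted p = 1.3e-04). Swap70 changed by -1.77 (SE 0.17, adjusted p = 0.00184) in FoB and by -1.47 (SE 0.16, adjusted p = 0.00238) in ABC. Without ABC WT replicate 1 the Swap70 difference in ABC had an adjusted p of 0.0539, in a range of 2.1e-06 to 0.0539 over the alternatives. Between ABC DKO and FoB DKO the log2 differences were 0.00 for Def6 and -0.02 for Swap70.

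**Figure D1:**
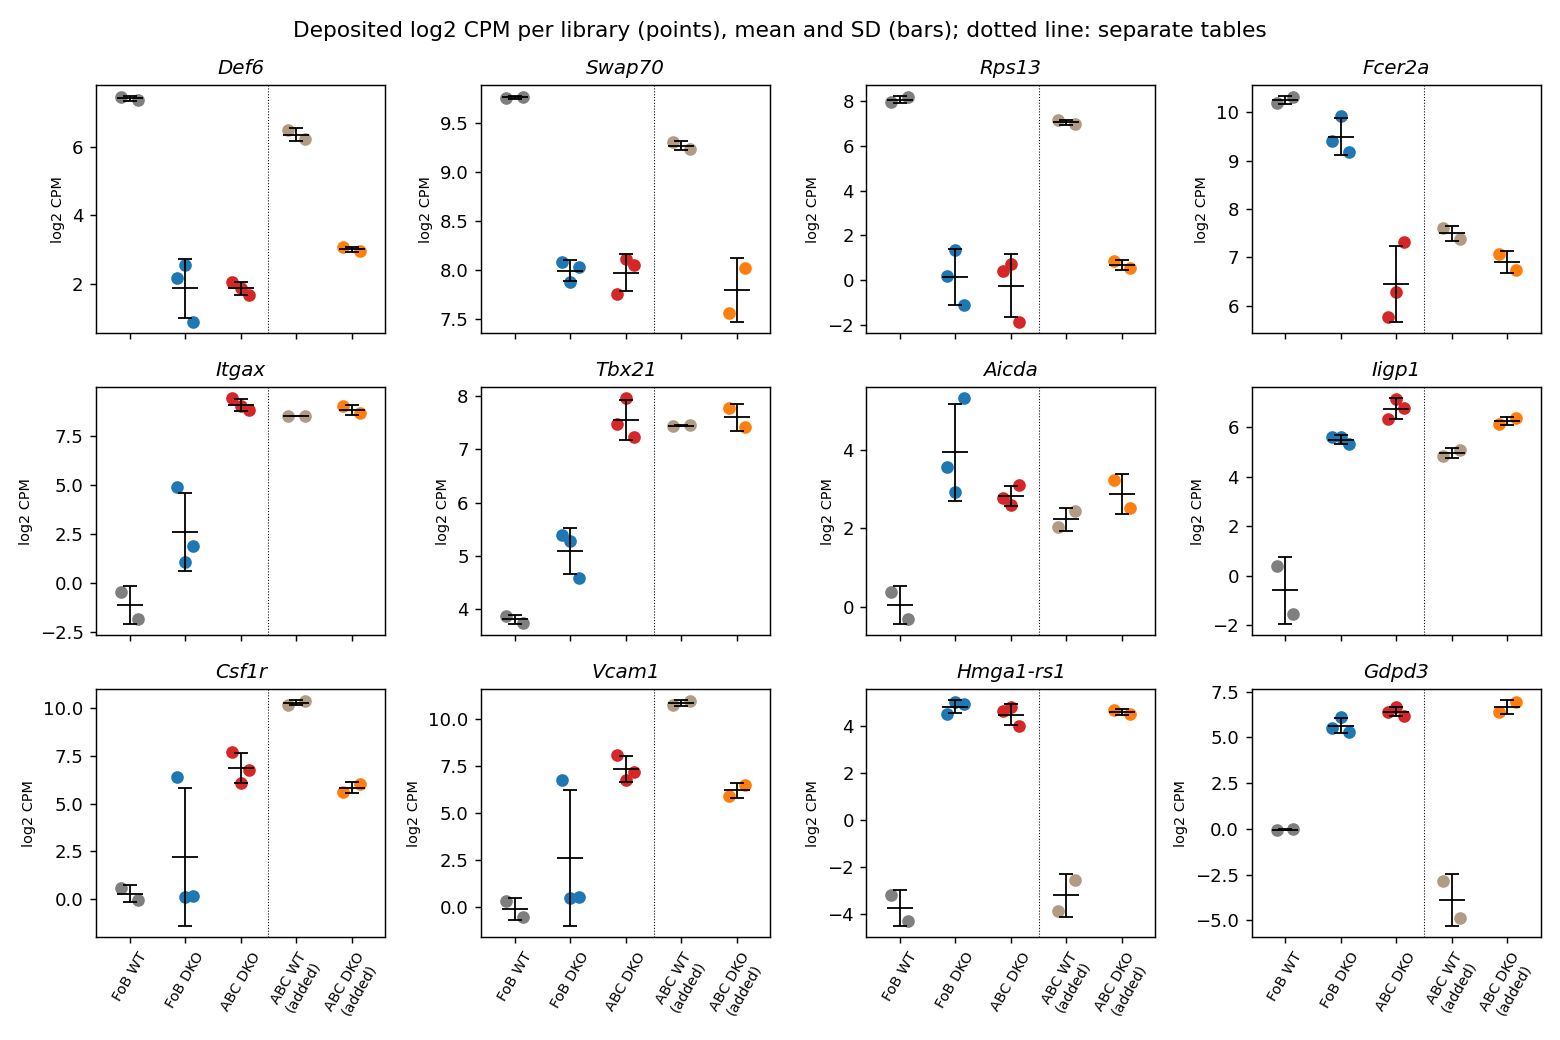
Deposited log2 CPM of 12 genes in each RNA-seq library (points) with the mean and SD of each group (bars); the dotted line parts the 2 tables. Def6 and Rps13 lie lower in every DKO library than in every WT library, while Csf1r and Vcam1 are high in ABC WT and in FoB DKO replicate 1 relative to the other FoB libraries.

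The first comparison asked what changes in follicular B cells that lack both SWEF proteins. Iigp1, an interferon-induced GTPase, rose from -0.59 ± 1.36 log2 CPM (SD, n = 2) in FoB WT to 5.50 ± 0.17 (SD, n = 3) in FoB DKO (limma adjusted p = 0.00102). Aicda, the deaminase of class switching and somatic hypermutation, rose from 0.03 ± 0.48 to 3.94 ± 1.24 (adjusted p = 0.00772). Nfil3, a transcription factor of lymphocyte maturation, rose from 0.45 ± 0.28 to 4.21 ± 0.85 (adjusted p = 0.00283), and Id3, an inhibitor of E proteins, fell from 8.11 ± 0.08 to 5.79 ± 0.83 (adjusted p = 0.0133). Gdpd3, a lysophospholipase D gene, rose from -0.04 ± 0.03 to 5.63 ± 0.41 (adjusted p = 4.7e-05), and Gprc5b, an orphan receptor gene at -3.77 ± 0.77 in FoB WT, close to the table's lowest value of -4.31, rose by 8.37 (SE 0.41, adjusted p = 5.8e-05). Bmf, a BH3-only cell death gene, fell from 6.03 ± 0.00 to 3.15 ± 0.80 (adjusted p = 0.00646), and Nucb2, which encodes a calcium-binding protein, from 5.07 ± 0.07 to 1.70 ± 0.39 (adjusted p = 0.00102). Among the genes of the sort markers, Ptprc rose by 1.01 (adjusted p = 0.0295), Itgam by 2.74 (adjusted p = 0.0101) and Itgax by 3.73 (adjusted p = 0.0314), the last from -1.14 ± 0.97 to 2.60 ± 2.01 with 4.87 in FoB DKO replicate 1. Cd19 (-0.61, adjusted p = 0.156) and Fcer2a (-0.76, adjusted p = 0.207) were not called.

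Of 27 gene lists tested with camera, 4 moved together in FoB DKO. Interferon-gamma response genes rose, with 10 of 20 members called higher and none lower, and 13 higher when adjusted over the list alone. Gbp7 (3.46), Gbp6 (1.90) and the class II transactivator Ciita (1.76) were among them, and the list had a camera adjusted p of 3.7e-05 and adjusted p = 0.978 with an estimated correlation. Germinal-centre genes rose, with 8 of 11 called higher and 9 adjusted over the list alone, among them Basp1 (3.08), Mybl1 (4.66) and Efnb1 (2.05). Their list had an adjusted p of 1.2e-04, and adjusted p = 0.990 with an estimated correlation. Cell-cycle genes rose as a list (adjusted p = 5.7e-05, and adjusted p = 0.990 with an estimated correlation), although only Ccna2 (3.00) and Mcm4 (1.29) of 25 members were called by limma and 0 when adjusted over the list alone (16 at an unadjusted p under 0.05). B cell identity genes fell, with 4 of 14 called lower and 8 adjusted over the list alone, namely Vpreb3 (-1.67), Pax5 (-0.99), Cd79a (-1.23) and Cd79b (-1.23). That list had an adjusted p of 0.0161, adjusted p = 0.990 with an estimated correlation and 0.171 after quantile normalization. The lowest adjusted p over the alternatives was 9.4e-07, 1.6e-05, 3.0e-10 and 0.00396 for these lists in turn, and the estimated correlation gave the highest. With fry the interferon-gamma list was called (adjusted p = 0.0264), the germinal-centre and B cell identity lists (both adjusted p = 0.0835) and the cell-cycle list (adjusted p = 0.256) were not, and ABC markers and plasma cell genes were called higher (adjusted p = 0.0270 and 0.0264).

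Single members rose or fell in lists that camera did not call as a whole in FoB DKO as fitted. With the exon length trend removed it called ABC markers (adjusted p = 0.0425) and plasma cell genes (adjusted p = 0.0439), and without FoB WT replicate 2 the type I interferon-stimulated genes (adjusted p = 0.0116). Of 13 ABC marker genes, Zeb2 (1.60), Tbx21 (1.28), Fas (1.47) and Nt5e (2.86) rose and 9 were not called (6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.211). Of 30 type I interferon-stimulated genes, Ifit3 (-2.00), Irf7 (-1.46) and Ifi35 (-1.10) were among 4 that fell and 1 rose (0 higher and 4 lower adjusted over the list alone). Among 9 immunoglobulin constant genes, Ighe (4.01), Ighg1 (3.87) and Ighg2b (2.38) rose and Iglc2 (-1.96) and Igha (-2.27) fell (4 higher and 3 lower adjusted over the list alone). Prdm1 (2.20), the driver of plasma cell differentiation, was among 4 of 13 plasma cell genes that rose, and the plasma cell marker Sdc1 (-1.81) fell (6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.221). Of 16 cytokine genes, Lta (-1.24), Ltb (-1.30) and Tnf (-1.40) were among 4 that fell and Csf1 (1.67) rose, while 11 were not called (2 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.303). Lta, Ltb and Tnf lie together 6.987 to 6.995 Mb from Def6. Rock1 (1.53), Dock10 (1.39) and Dock8 (0.81) rose among 28 Rho and actin genes, with none lower and 3 when adjusted over the list alone (list median -0.14, mean 0.03). Library means of the cell-cycle list were 5.88, 4.52 and 7.22 log2 CPM in FoB DKO replicates 1, 2 and 3 and 4.32 and 4.10 in FoB WT. Germinal-centre means moved with them, at 5.04, 4.18 and 6.61 against 2.83 and 2.36. Of 17 myeloid marker genes limma called 0, also when adjusted over the list alone, and 1 had an unadjusted p under 0.05. Their mean was 3.95 in FoB DKO replicate 1 against -0.45 and -0.48 in replicates 2 and 3, and Csf1r, chosen here after its values were seen, read 6.40 there against 0.10 and 0.15. Erythroid markers, also genes of another cell type and too few for the list test, were lower in FoB DKO, with Car2 (-2.40) and Hbb-bs (-3.54) of 3 called and all 3 when adjusted over the list alone. Their library means were -1.15, -0.22 and -0.25 log2 CPM in FoB DKO against 1.86 and 2.57 in FoB WT. Of 4 dendritic genes 2 were called higher and 0 lower, with 2 higher and 1 lower adjusted over the list alone. Of 5 natural killer genes 1 was called higher, and of 8 T cell genes 0 were called.

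Across all genes limma called 2432 of 11540 in FoB DKO, 1429 higher and 1003 lower, with 4599 at an unadjusted p under 0.05. The share of higher genes was 58.8%, and 59.9% after quantile normalization. It was 50.9% with limma-voom on recovered reads and 51.6% with replicate numbers as blocks. The libraries of the 2 groups did not overlap for 59.3% of genes, where chance gives 20%. Leaving out any 1 library moved the count by more than 1.5 times, to 190 genes without FoB WT replicate 1 and 44 without replicate 2. Without FoB DKO replicates 1, 2 and 3 the counts were 1540, 3765 and 1428. Of the 94 named calls, 71 were lost without FoB WT replicate 1 and 82 of 93 without replicate 2, while Def6, Swap70, Iigp1, Gdpd3, Gprc5b, Nucb2, Nfil3, Gbp7, Hmga1-rs1, Adm and mt-Atp8 were kept under every setting. Genes called higher had a median exon length of 5807 bases and those lower 2070 bases. Across all genes the fold change followed exon length with a Spearman rho of 0.442, against -0.109 for ABC DKO over FoB DKO and 0.136 for ABC DKO over ABC WT. Per library the rho with exon length was -0.34 and -0.377 in FoB WT and 0.47, -0.034 and 0.256 in FoB DKO. The trend thus ran with genotype across whole libraries. Of the 2432 calls 1250 remained after that trend was removed from each library, when 1574 genes were called.

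The next comparison asked how ABC differ from FoB when both lack the SWEF proteins. Itgax, the gene of the sort marker CD11c, rose from 2.60 ± 2.01 log2 CPM (SD, n = 3) in FoB DKO to 9.09 ± 0.30 (SD, n = 3) in ABC DKO (limma adjusted p = 0.00346). Itgam, the gene of CD11b, rose from 3.87 ± 0.96 to 8.63 ± 0.12 (adjusted p = 8.5e-04), and Fcer2a, the gene of CD23, fell from 9.49 ± 0.38 to 6.45 ± 0.79 (adjusted p = 0.00258). Tbx21, the transcription factor gene of T-bet that marks ABC, rose from 5.09 ± 0.43 to 7.55 ± 0.37 (adjusted p = 0.00157), and Zeb2, a repressor of the same lineage, from 5.80 ± 0.42 to 8.05 ± 0.23 (adjusted p = 0.00165). S1pr5, a sphingosine phosphate receptor gene, rose from -1.74 ± 1.62 to 4.47 ± 0.25 (adjusted p = 0.00267), and Art3, an ADP-ribosyltransferase gene, from -1.65 ± 0.41 to 5.15 ± 0.19 (adjusted p = 2.4e-04). Bcl6, a transcriptional repressor that germinal-centre B cells need to form, fell from 7.37 ± 0.22 to 5.76 ± 0.34 (adjusted p = 0.00266). Il5ra, the interleukin-5 receptor gene, fell from 3.29 ± 0.48 to 0.61 ± 0.48 (adjusted p = 0.00284), and Pde2a, a phosphodiesterase gene, from 6.32 ± 0.62 to 3.40 ± 0.28 (adjusted p = 0.00148). Cd19 (0.25, adjusted p = 0.651) and Ptprc (0.02, adjusted p = 0.973) were not called.

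Camera called 12 of 27 lists in ABC DKO, and 2 of them, ABC markers and plasma cell genes, were also called with an estimated correlation. With fry 8 of the 12 were called, and the follicular (adjusted p = 0.296), germinal-centre, myeloid and unfolded protein lists (each adjusted p = 0.0715) were not. For each list the lowest adjusted p over its alternatives follows the first value, and the highest was that with an estimated correlation. ABC markers rose in 10 of 13 genes, 11 adjusted over the list alone, with Lgals1 (3.39) and Fcrl5 (2.37) beside Tbx21 and Zeb2 (adjusted p = 2.0e-10, lowest 1.5e-11, and adjusted p = 0.0210 with an estimated correlation). Plasma cell genes rose in 6 of 13, 9 adjusted over the list alone, with Creb3l2 (2.29), Sdc1 (2.02) and Prdm1 (2.56) among them (adjusted p = 5.6e-06, lowest 3.0e-06, and adjusted p = 0.0480 with an estimated correlation). B1 cell genes rose in 6 of 9, all 9 adjusted over the list alone, with Spn (3.18), Zbtb32 (5.32) and Bhlhe41 (4.57) among them (adjusted p = 3.7e-09, lowest 2.7e-09, and adjusted p = 0.0532 with an estimated correlation). Natural killer markers, genes of another cell type, rose in 4 of 5, all 5 adjusted over the list alone, with Prf1 (2.74) and Nkg7 (4.22, to only 0.58 ± 0.10 log2 CPM) among them (adjusted p = 2.4e-05, lowest 1.6e-05, and adjusted p = 0.0756 with an estimated correlation). Immunoglobulin constant genes rose in 5 of 9, 6 adjusted over the list alone, with Igha (4.04) among them (adjusted p = 8.6e-05, lowest 9.3e-07, and adjusted p = 0.286 with an estimated correlation). Inhibitory receptor genes rose in 7 of 17 and fell in 1, 11 and 2 adjusted over the list alone, with Fcgr2b (1.48) and Lag3 (3.26) higher (adjusted p = 1.6e-04, lowest 1.2e-05, and adjusted p = 0.358 with an estimated correlation). Cytokine genes rose in 6 of 16 and fell in 1, 9 and 3 adjusted over the list alone, with Cxcl10 (4.56) and Ccl22 (5.89) higher and Lta (-1.10) lower (adjusted p = 0.00496, lowest 0.00139, and adjusted p = 0.357 with an estimated correlation). Without ABC DKO replicate 1 the cytokine list had an adjusted p of 0.0652. Trafficking receptors rose in 6 of 20, 7 higher and 2 lower adjusted over the list alone, with Cd44 (2.06) and Itgb1 (3.12) among them (adjusted p = 0.00535, lowest 1.7e-04, adjusted p = 0.505 with an estimated correlation and 0.193 without FoB DKO replicate 3). Unfolded protein genes rose in 4 of 18, 5 adjusted over the list alone, with Edem1 (1.31) among them (adjusted p = 0.00163, lowest 3.7e-05, adjusted p = 0.555 with an estimated correlation and 0.0761 without FoB DKO replicate 1).

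Lower in ABC DKO were the germinal-centre and follicular lists. Germinal-centre genes fell in 3 of 11, 8 adjusted over the list alone, with Bcl6 (-1.61) among them (adjusted p = 5.6e-06, lowest 1.2e-08, and adjusted p = 0.472 with an estimated correlation). Library means of this list were 3.53, 3.01 and 3.97 log2 CPM in ABC DKO replicates 1, 2 and 3. These lay below FoB DKO (5.04, 4.18 and 6.61) but above FoB WT (2.83 and 2.36). The fall is thus relative to FoB DKO libraries that were themselves raised over FoB WT. Follicular genes fell in 3 of 13 and rose in 1, 5 and 1 adjusted over the list alone, with Cd55 (-1.96) lower (adjusted p = 0.0317, and adjusted p = 0.709 with an estimated correlation). The follicular list had an adjusted p of 0.0779 with replicate numbers as blocks, 0.292 without FoB DKO replicate 2 and 0.124 without ABC DKO replicate 1, in a range of 0.00359 to 0.709. Myeloid markers, here genes of another cell type, rose in 4 of 17, with 16 adjusted over the list alone and Apoe at 2.23 (adjusted p = 4.5e-08, lowest 3.2e-20, and adjusted p = 0.472 with an estimated correlation). Their library means were 5.44, 4.50 and 4.40 log2 CPM in ABC DKO replicates 1, 2 and 3. Bulk values do not show which cells held the RNA of the lists that rose. RNA of other cells may add to them, which was not tested. T cell markers, not called as a list (adjusted p = 0.350, median 2.125), rose in 2 of 8, namely Il7r (4.597) and Tcf7 (2.86), with 3 higher and 2 lower adjusted over the list alone. The genes of the co-stimulatory ligands Cd80 (3.84) and Cd86 (1.34) rose and Icosl (-1.78) fell, while Tlr7 (1.13) and Tlr9 (1.10) rose in a Toll-like receptor list that was not called (4 of 17 higher, 4 adjusted over the list alone, adjusted p = 0.110). Camera called that list after quantile normalization (adjusted p = 0.0293) and without FoB DKO replicate 2 (adjusted p = 0.0451). With fry it was not called (adjusted p = 0.0607).

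In this comparison limma called 1026 of 11540 genes, 817 higher and 209 lower, with 2636 at an unadjusted p under 0.05. The groups did not overlap for 24.9% of genes, where chance gives 10%. With replicate numbers as blocks 1867 genes were called, including all 1026 in the same direction, and the 79.6% share of higher genes was 67.6% after quantile normalization, which moved the median of all genes from -0.06 to -0.11. Fitting only the 2 groups compared gave 677 genes, and 521 and 445 were called without ABC DKO replicates 1 and 2. Of 86 named calls 51 were kept under every setting, among them Itgax, Itgam, Fcer2a, Tbx21, Zeb2, Bcl6, Spn, Zbtb32, Cd80, Tlr7 and Igha. Apoe lost its call without FoB DKO replicate 3 or without ABC DKO replicate 1 or 2.

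**Figure D2:**
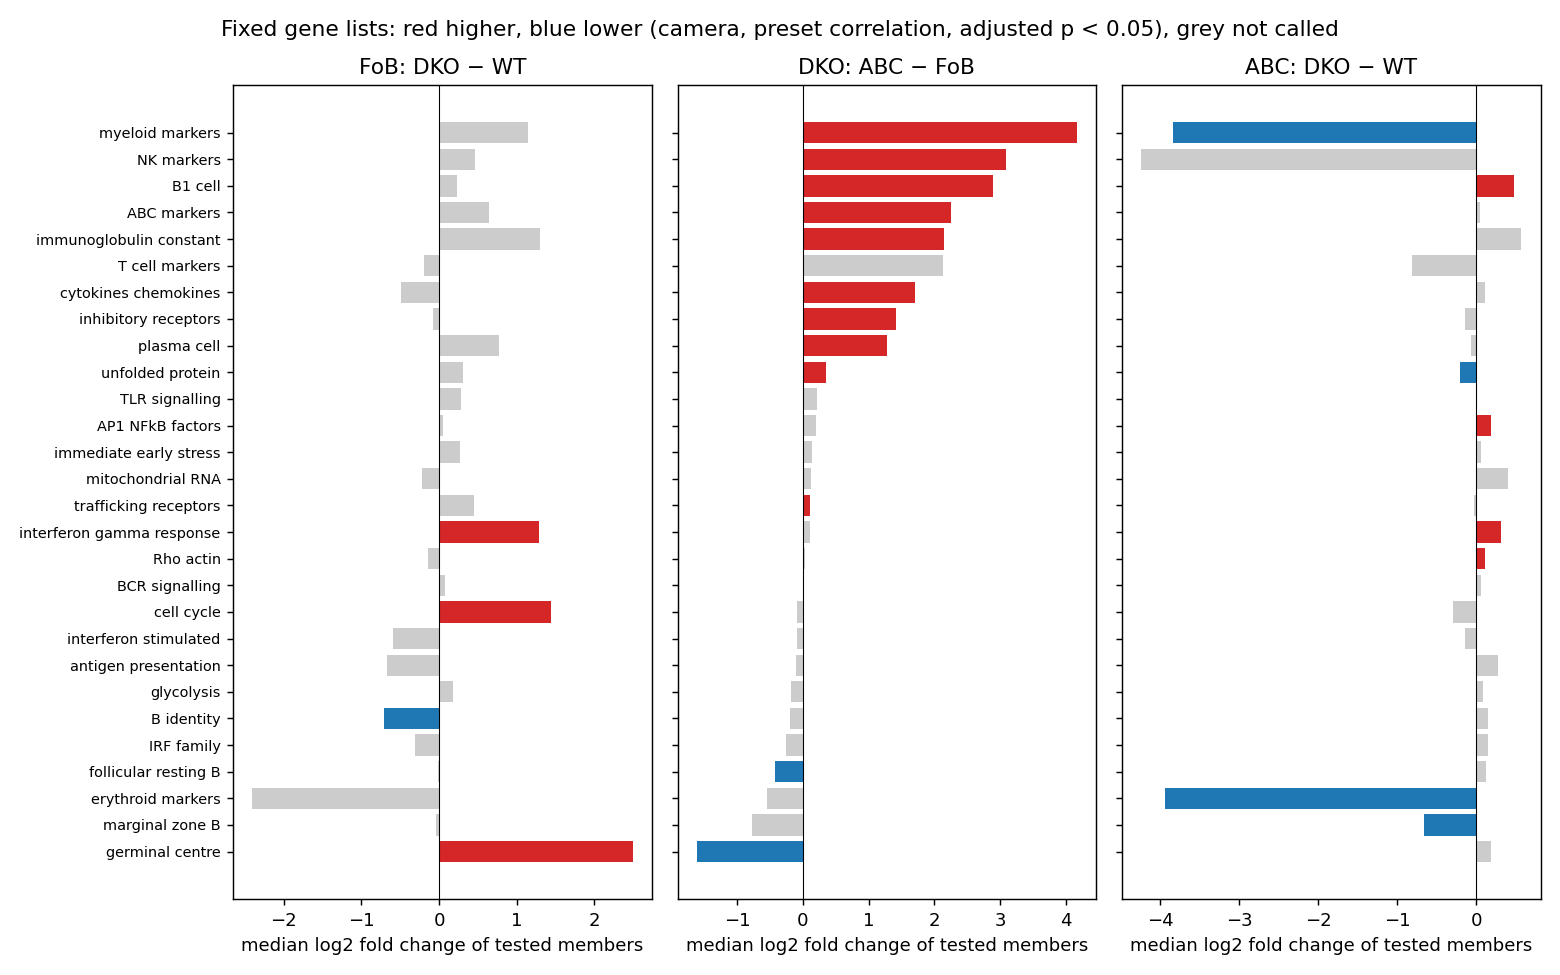
Median log2 fold change of each fixed gene list in the 3 RNA-seq comparisons, with lists called by camera drawn in red (higher) or blue (lower). ABC markers rise between FoB DKO and ABC DKO (median 2.25), and myeloid and erythroid markers fall between ABC WT and ABC DKO (medians -3.84 and -3.94).

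The additional libraries allowed ABC DKO to be compared with ABC WT. Gdpd3 rose here too, from -3.88 ± 1.43 log2 CPM (SD, n = 2) in ABC WT, near that table's lowest value of -4.89, to 6.65 ± 0.37 (SD, n = 2) in ABC DKO (limma adjusted p = 4.0e-04). Iigp1 rose from 4.96 ± 0.19 to 6.24 ± 0.17 (adjusted p = 0.00255). Thsd7a, a thrombospondin-domain gene, rose from -0.62 ± 1.00 to 3.84 ± 0.55 (adjusted p = 0.00371), and the AP-1 gene Jun from 5.14 ± 0.14 to 6.43 ± 0.03 (adjusted p = 9.2e-04). Csf1r, the macrophage growth factor receptor gene, fell from 10.28 ± 0.13 to 5.83 ± 0.29 (adjusted p = 9.7e-05), Cd163, a haemoglobin scavenger receptor gene, from 6.56 ± 0.22 to 0.32 ± 0.10 (adjusted p = 6.3e-05), and Ptgis, the prostacyclin synthase gene, from 5.05 ± 0.01 to -2.44 ± 1.19 (adjusted p = 6.4e-04). Igha fell by 2.62 from 11.62 ± 0.71 (adjusted p = 0.00346), and Ighg1, a class-switched heavy chain gene, rose from 6.50 ± 0.21 to 9.53 ± 0.83 (adjusted p = 0.00374). Of the sort markers Itgam rose by 0.82 (adjusted p = 0.00688), whereas Itgax (0.30), Cd19 (0.10), Ptprc (0.11) and Fcer2a (-0.59) were not called.

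Camera called 8 of 26 lists between ABC DKO and ABC WT, and 0 with an estimated correlation or with fry. It compares each list with the other genes, and 846 genes were called lower here against 310 higher, so a list called higher is higher relative to these. The lists called higher had median log2 changes of 0.31 (interferon-gamma), 0.48 (B1 cell), 0.19 (AP-1 and NF-kB) and 0.11 (Rho and actin). Myeloid markers fell in 16 of 17 genes, 17 adjusted over the list alone, with Cd68 (-3.34), Hmox1 (-4.56) and Vcam1 (-4.63) beside Csf1r (adjusted p = 2.1e-18, lowest 4.5e-26, and adjusted p = 0.591 with an estimated correlation). Erythroid markers fell in 7 of 7, all 7 adjusted over the list alone, with Hba-a1 (-3.94) and Hbb-bs (-4.12), members of gene families with near-identical copies, among them (adjusted p = 2.1e-07, lowest 1.5e-10, and adjusted p = 0.591 with an estimated correlation). Markers of other cells too few for the list test fell only in part. Of 3 natural killer genes Klrk1 (-4.24) and Gzma (-4.67) were called lower and Prf1 (0.44) was not called. Of 3 T cell genes Cd4 (-4.23) was called lower, and Lck (0.23) and Cd3g (-0.81) were not called. Of 4 dendritic genes 1 was called higher and 2 lower, with 2 higher and 2 lower adjusted over the list alone (median 0.117). Interferon-gamma response genes rose in 4 of 20 and fell in 1, 8 and 1 adjusted over the list alone, with Socs1 (1.35) higher and Cxcl9 (-2.75) lower (adjusted p = 1.2e-04, lowest 1.3e-05, and adjusted p = 0.591 with an estimated correlation). B1 cell genes rose in 3 of 6, 5 adjusted over the list alone, with Plscr1 (1.21) and Zbtb32 (1.06) among them (adjusted p = 3.1e-04, lowest 8.7e-05, and adjusted p = 0.591 with an estimated correlation). Marginal zone genes fell in 4 of 8, 5 adjusted over the list alone, with Myof (-2.00) and Cd1d1 (-1.60) among them (adjusted p = 0.00134, lowest 5.9e-04, and adjusted p = 0.591 with an estimated correlation). AP-1 and NF-kB factor genes rose in 3 of 15 and fell in 1, the same adjusted over the list alone, with Nfil3 (1.91) higher and Maf (-4.12) lower (adjusted p = 0.00611, lowest 0.00191, adjusted p = 0.591 with an estimated correlation and 0.0672 after quantile normalization). Unfolded protein genes fell in 7 of 18, 8 lower and 1 higher adjusted over the list alone, with Pdia6 (-0.67) and Sdf2l1 (-0.68) among them (adjusted p = 0.0117, lowest 5.9e-04, adjusted p = 0.804 with an estimated correlation and 0.159 without ABC WT replicate 2). Rho and actin genes rose in 3 of 27, 3 adjusted over the list alone, namely Dock10 (0.86), Rhoh (0.49) and Dock8 (0.38) (adjusted p = 0.0188, lowest 0.0122, adjusted p = 0.804 with an estimated correlation, 0.171 without ABC WT replicate 2 and 0.207 after quantile normalization). ABC markers were not called as a list (adjusted p = 0.408), with Fas (0.85) and Il21r (0.69) higher and Cd86 (-0.79) lower among 13, and 3 higher and 2 lower adjusted over the list alone.

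Here limma called 1156 of 9684 genes, 310 higher and 846 lower, with 2320 at an unadjusted p under 0.05. The groups did not overlap for 53.3% of genes, where chance gives 33.3%. The share of higher genes was 26.8%, and 40.0% after quantile normalization, with 38.5% when libraries were centred on their median gene. Without ABC WT replicate 1 or 2, 376 genes were called each time, 47 and 46 of 81 named calls were lost, and 13 lists were called without ABC DKO replicate 1. Gdpd3, Iigp1, Thsd7a, Jun, Csf1r, Cd163, Ptgis and Igha were among 39 of 90 named calls kept under every setting, while Ighg1, Fas, Il21r, Cd86, Socs1, Zbtb32, Nfil3, Pdia6, Sdf2l1, Dock10, Rhoh and Dock8 lost theirs without either ABC WT library, and Itgam without ABC WT replicate 1.

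Placed side by side without a test of the difference, the DKO effects in FoB and ABC could be read for 9641 genes. Of these 111 were called higher in both cell types, where independent lists would share 41.3, and 74 lower in both, against 78.5. Another 59 were higher in FoB and lower in ABC (106.9 for independent lists) and 5 the reverse (30.3). The fold changes had a Pearson r of -0.063 and a Spearman rho of 0.106 across genes, which are not independent replicates. Without FoB WT replicate 1 or 2 the genes called the same way numbered 27 and 14 in place of 185, and without ABC WT replicate 1 or 2 they numbered 54 and 58.

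Several of the genes changed in both cell types lay near the deleted loci. Within 10 Mb of Def6 or Swap70, 23 of 350 genes (6.57%) were called in the same direction in both cell types, against 160 of 9289 (1.72%) elsewhere (odds ratio 4.01, Fisher's exact p = 1.8e-07, 2-sided, over genes, which are not replicates). The near genes come from stretches around only these loci, where neighbours may change together, so that p does not measure a spread between loci. Hbb-bs, an erythroid marker, and Lst1 (-1.42 and -2.79), expressed in myeloid cells and named after its values were seen, are among the 23, so RNA of other cells can enter this count, and without both the odds ratio was 3.66 (Fisher's exact p = 2.2e-06, a test chosen after the data were seen). Genes between 10 and 20 Mb away, also compared after the data were seen, were called in the same direction for 7 of 208 (3.37%) against 1.69% farther off (odds ratio 2.03, Fisher's exact p = 0.0938), and Gdpd3, at 16.54 Mb from Swap70, is 1 of the 7. Gprc5b, 8.75 Mb from Swap70, could not be compared, as it is in the first table alone. Between ABC DKO and FoB DKO 7.71% of the near genes and 8.54% of the others were called. Adm, the adrenomedullin gene (mm10 chromosome 7, 110627660 to 110629820), 0.406 Mb from Swap70, rose by 5.06 in FoB and 3.86 in ABC. Wee1, a cell-cycle kinase gene 0.0994 Mb away and named after its values were seen, rose by 3.00 and 1.47. Rps13, a ribosomal protein gene on chromosome 7 from 116331506 to 116334190, lies 6.11 Mb from Swap70. Its counted level fell from 8.06 ± 0.15 to 0.14 ± 1.24 log2 CPM in FoB (limma adjusted p = 0.00271). In ABC it fell from 7.05 ± 0.11 to 0.69 ± 0.22 (limma adjusted p = 5.5e-05). Means were 267.9 CPM in FoB WT and 133.1 in ABC WT, against 1.33 in FoB DKO and 1.02 and 1.59 in ABC DKO of the first and the separate table. Whether its RNA or the assignment of its reads changed was not tested. Without FoB WT replicate 2 the Rps13 call in FoB was lost. Nucb2, 6.28 Mb away, changed by -3.38 in FoB and -1.31 in ABC. Near Def6, the dynein gene Dnah8 rose by 2.98 and 2.78, and H2-T10, a class I gene with close relatives that can share reads, by 1.45 and 4.08. Hmga1, a chromatin protein gene 0.651 Mb from Def6 and named after its values were seen, fell from 63.9 ± 0.847 CPM (SD, n = 2) to 20.2 ± 4.23 (SD, n = 3) in FoB, while its near copy on another chromosome, Hmga1-rs1, went from 0.0283 ± 0.0401 to 28.15 ± 5.15 (limma adjusted p = 4.7e-05). The counting could split reads of that pair either way, so the level of each is uncertain.

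**Figure D3:**
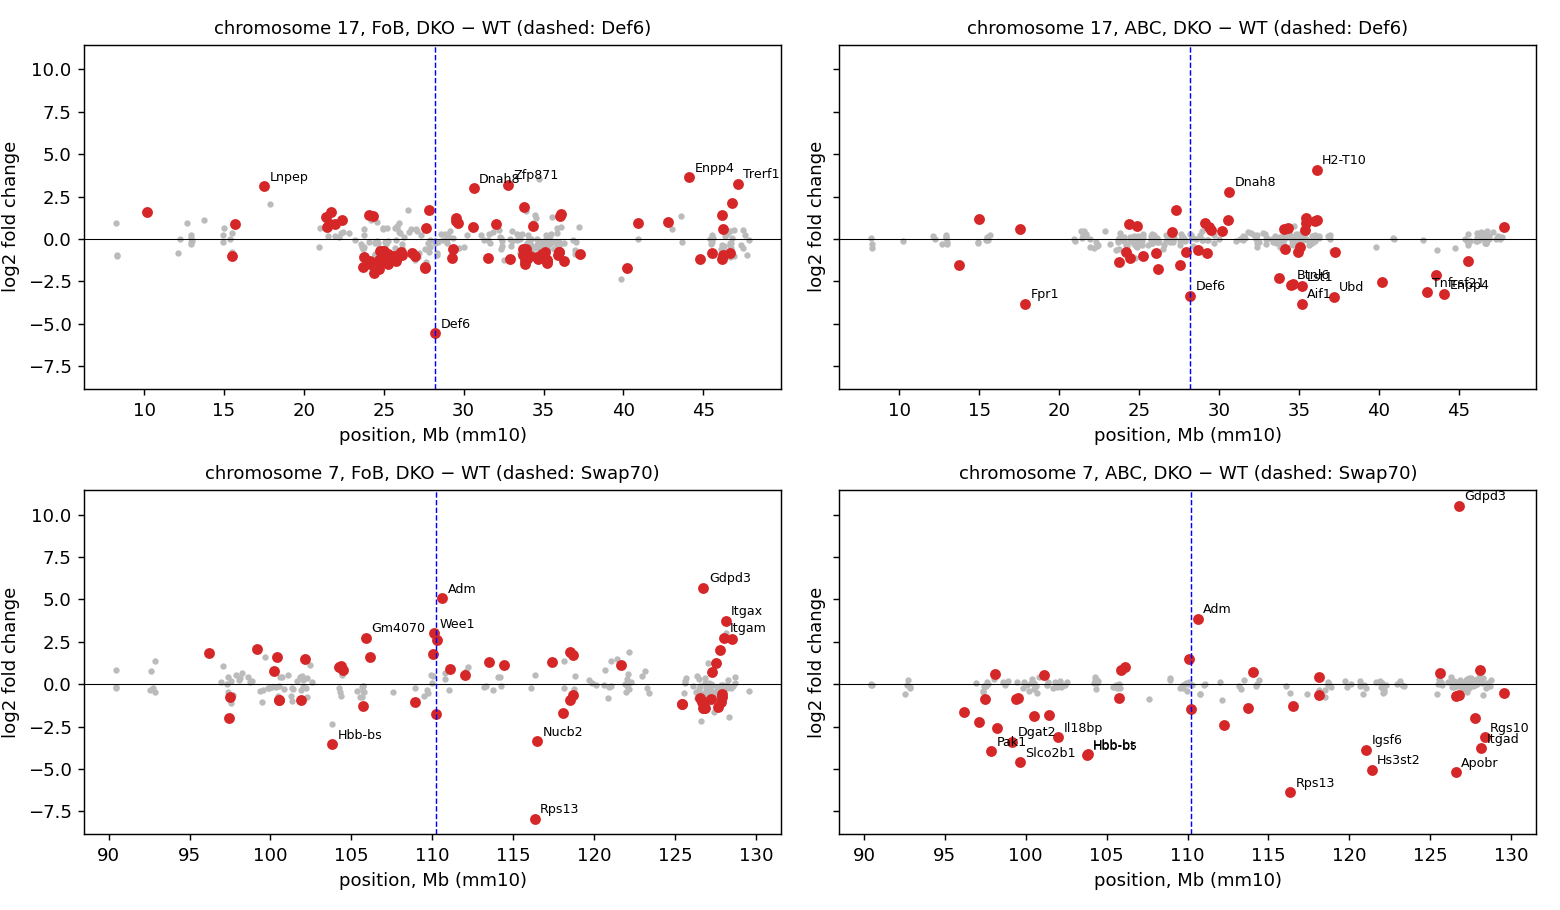
Log2 fold change of DKO over WT in FoB and in ABC for genes within 20 Mb of Def6 (mm10 chromosome 17) and Swap70 (chromosome 7), plotted by gene start. Rps13 (-7.92 in FoB, -6.37 in ABC) and Adm (5.06 and 3.86) are among the genes that moved the same way in both cell types.

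The first comparison and the next one share the FoB DKO libraries. Their fold changes had a Pearson r of 0.183 across genes, where simulated data with the shared libraries and no effects gave -0.449, and a covariance of 0.175 against -0.101. The simulation drew every library independently, without the correlation between FoB DKO and ABC DKO libraries of the same number (r = 0.709, 0.614 and 0.362), so its values are not those expected of these libraries without changes. Genes higher in both numbered 111 (101.2 for independent lists), lower in both 25 (18.2), higher then lower 27 (25.9) and lower then higher 53 (71.0). The 3 FoB DKO libraries could not be parted into separate sets of at least 2, so what the sharing adds to the opposite changes or takes from the same-direction ones was not measured.

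The chromatin comparison asked which sites are open in ABC DKO or FoB DKO alone. The FoB DKO lists held 180731 and 177819 peaks, the ABC DKO lists 114220 and 114955, and the ABC WT list 236343, from 156.3, 163.7, 163.1, 162.2 and 126.8 M tags. Peaks were 56 bp wide by the headers in FoB DKO and ABC WT and 162 bp in ABC DKO. By the headers the minimum distance between peaks was 112 bp in FoB DKO and ABC WT and 324 bp in ABC DKO. Tag thresholds were 14 and 15 in FoB DKO, 23 and 26 in ABC DKO and 13 in ABC WT. Of 95237 peaks found in both ABC DKO lists, 8460 (8.90%) overlapped no FoB DKO peak (ABC-only), and of 148538 in both FoB DKO lists 51505 (34.7%) overlapped no ABC DKO peak (FoB-only). With the same number of peaks taken from the top of every list these counts were 25221 and 27386. The DKO lists have no score to rank by, so their line order, not documented as a strength, was used. It followed the tag order of overlapping ABC WT peaks with a Spearman rho of 0.774 and 0.772 in FoB DKO but 0.473 and 0.522 in ABC DKO, so these counts depend on an uncertain ranking. Without ABC DKO replicate 1 or 2 the ABC-only peaks numbered 18143 and 14905. No test on single peaks was possible from lists.

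The labels give mm10 for the peak coordinates, which was not checked separately, so every peak-to-gene distance here and below depends on it. Near Itgax, 2 ABC-only peaks lay outside the gene on chromosome 7, 1.1 and 2.2 kb away. They lay at 128151726 to 128151888 and at 128152825 to 128152987, and 1 FoB-only peak lay 4.2 kb away. Itgam, higher in ABC as well, had 2 FoB-only peaks and 0 ABC-only peaks. Fcer2a had an FoB-only peak within the gene, at chromosome 8, 3693954 to 3694010. Zeb2 held ABC-only peaks within the gene on chromosome 2, at 45009071 to 45009233 and at 45087310 to 45087472, and also 10 FoB-only peaks within 20 kb, of which that at 45009245 to 45009301 lay directly beside the first ABC-only peak. Cd80 (chromosome 16, 38471954 to 38472116) and Cd86 (chromosome 16, 36621233 to 36621395 and 36615361 to 36615523) had ABC-only peaks within the gene, and Il21r had 3, while FoB-only peaks within 20 kb numbered 8 for Cd80, 5 for Cd86 and 4 for Il21r. Of 13 ABC marker genes, 6 had an ABC-only peak (10 peaks) and 9 an FoB-only peak (59 peaks). Of 13 follicular genes, 4 had an ABC-only peak (10 peaks) and 9 an FoB-only peak (86 peaks), 34 of them at Foxp1 and 28 at Bach2. Tbx21 had neither kind. Whether peaks within genes fell in exons or introns was not resolved. By mean line order, which is not documented as a strength, the first ABC-only peak lay in Zbtb20 at chromosome 16, 42875681 to 42875843, with FoB-only peaks on either side of it at 42875612 to 42875668 and at 42875866 to 42875922.

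Genes higher in ABC DKO more often had ABC-only peaks nearby than uncalled genes did. Genes lower in ABC DKO had them within 20 kb at nearly the same share (67 of 209, 32.1%). These shares therefore do not part higher from lower genes. An ABC-only peak lay within 20 kb of 272 of 817 higher genes (33.3%) and of 2906 of 10514 uncalled genes (27.6%), an odds ratio of 1.31 (Fisher's exact p = 6.8e-04, 2-sided, over genes, which are not replicates). The p ran from 5.6e-05 to 0.0211 over the alternatives other than a 50% reciprocal overlap. Under that overlap the peak widths leave 92246 of 92247 replicated ABC DKO peaks as ABC-only and 130951 of 130952 FoB DKO peaks as FoB-only, so its odds ratio of 1.12 (Fisher's exact p = 0.314) compares nearly all peaks and does not bear on ABC-only ones. An FoB-only peak lay near 174 of 209 lower genes (83.3%) against 74.1% of uncalled genes (odds ratio 1.74, Fisher's exact p = 0.00231; 1.36 and p = 0.472 within 100 kb), where the lower genes had a median length of 34.7 kb and the uncalled 22.1 kb. Of the higher genes 70.4% had an FoB-only peak (odds ratio 0.829, Fisher's exact p = 0.0206; odds ratios from 0.792 to 1.05 over the alternatives other than the reciprocal overlap), and for the lower genes with ABC-only peaks the odds ratio was 1.24 (Fisher's exact p = 0.161).

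The ABC WT list, from 1 library, held 89.5% of the replicated ABC DKO peaks (95% Clopper-Pearson interval 89.3% to 89.6%) and 85.9% of the replicated FoB DKO peaks (85.7% to 86.0%). It held 54.2% of the ABC-only peaks (53.1% to 55.3%) and 76.99% of the FoB-only peaks (76.6% to 77.4%). Among peaks named above, the ABC-only peaks of Cd80 and Cd86, the Fcer2a peak in the gene and the Zbtb20 peaks were in the ABC WT list, as were 5 of 8 FoB-only peaks of Cd80 and 3 of 5 of Cd86, whereas only 1 of 2 ABC-only peaks each at Itgax and Zeb2 and 1 of 3 at Il21r were. Of the ABC WT peaks 27.4% overlapped no DKO peak. With the same number of peaks from every list, taken by that line order in the DKO lists, the ABC-only share was 14.6% and the FoB-only share 66.5%.

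**Figure D4:**
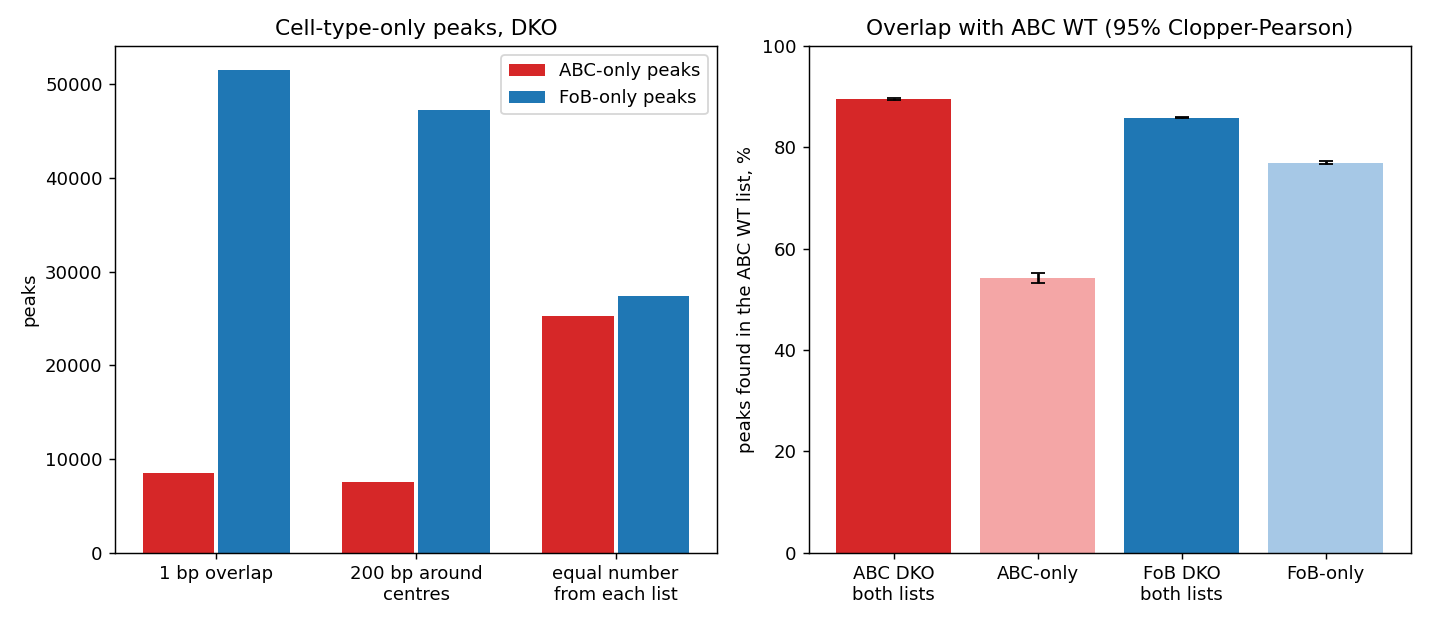
Numbers of ABC-only and FoB-only peaks under 3 settings, and the percentage of each peak class present in the ABC WT list with 95% Clopper-Pearson intervals. FoB-only peaks outnumber ABC-only peaks as reported (51505 against 8460), and the numbers draw close with lists of the same length (27386 against 25221).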

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

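Items for this part were found by screening 72 lists and genes for DKO effects of opposite sign in every library of FoB and of ABC, and the differences were not tested. B cell identity genes (14 members) had a mean log2 difference of -0.62 in FoB DKO, from -0.87 to -0.29 over the libraries, and of 0.14 in ABC DKO, from 0.05 to 0.22, a difference of 0.753. Germinal-centre genes (10 members in both tables) had 2.73 in FoB DKO, from 1.61 to 4.06, and -0.11 in ABC DKO, from -0.20 to -0.03, a difference of -2.837. In ABC DKO the median of that list was 0.19 and its mean -0.11, so its sign depends on the summary. Toll-like receptor signalling genes (17 members) had 0.24 in FoB DKO, from 0.10 to 0.38, and -0.16 in ABC DKO, from -0.24 to -0.08, a difference of -0.402. The median of this list was 0.288 in FoB DKO but only -0.008 in ABC DKO, where 2 members were called lower and 15 were not called. Camera called the list in neither (adjusted p = 0.235 and 0.830). Neither technical nor biological explanations were weighed for these, and the FoB and ABC effects come from separate tables.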

How the results depend on the processing

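Alternatives with limma-voom, the exon length trend, median centring, 200 bp windows, combined settings and number 1 left out of both groups were chosen after seeing the data. Not run were DESeq2, RLE scaling and the interaction test, which the plan kept for deposited counts although the recovered reads would have allowed them, a block for peaks, which needs counts per region, and motif content with GC matching or wider windows, which needs a genome. Where a group keeps 1 library, that library is assumed to vary like the other groups.

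Genes called in FoB DKO against WT (2432) numbered 44 to 3765 when libraries were left out, 1574 with the exon length trend removed and 1424 with a log2 fold change of at least 1. Genes called in ABC DKO against FoB DKO (1026) numbered 445 to 1213 with libraries left out and 677 with only the 2 groups fitted. Genes called in ABC DKO against ABC WT (1156) numbered 376 to 1472 with libraries left out and 701 with a log2 fold change of at least 1. Genes called the same way in both cell types (185) numbered 14 to 244 with libraries left out. A fold minimum lowers a count by construction, and fewer libraries leave fewer degrees of freedom. The cause of the other changes was not tested.

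With a block by replicate number, ABC DKO against FoB DKO gave 1867 genes, 2065 with the exon length trend also removed and 2097 with only the 2 groups fitted. FoB WT and FoB DKO, and ABC WT and ABC DKO, share only a number (r = 0.172 and 0.22, and 0.014), and a block gave 3771 and 1014 genes there. The follicular list had an adjusted p of 0.0779 with the block, in a range of 0.00359 to 0.709.

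Called lists numbered 0 of 4, 2 of 12 and 0 of 8 for these comparisons with an estimated correlation, and fry called 1, 8 and 0 of the same 4, 12 and 8. For ABC DKO against ABC WT, where camera called 8, the lists numbered 8 to 13 with libraries left out. The cell-cycle list in ABC DKO against FoB DKO, not called (adjusted p = 0.431), was lower without FoB DKO replicate 2 and higher without FoB DKO replicate 3 (adjusted p = 0.00747), with leave-one-out values from 4.0e-06 to 0.598. The gene mt-Atp8 there went from 0.19 to -1.14 with the exon length trend removed (adjusted p = 0.0476) and to -1.14 with the block as well (adjusted p = 0.00906), in a range of 0.00906 to 0.756. The cause was not tested.

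ABC-only and FoB-only peaks (8460 and 51505) numbered 92246 and 130951 with a 50% reciprocal overlap, which widths of 57 and 163 bp exclude between the cell types by construction. They numbered 25221 and 27386 with the same number of peaks from every list, and 24508 and 24065 with 200 bp windows as well. The first part of each list gave 33800 FoB-only and 8700 ABC-only peaks. This setting and that with the same number of peaks rank the DKO peaks by line order, which is not documented as a strength. Leaving out libraries gave 11533 to 18143 ABC-only and 60162 to 73773 FoB-only peaks. The ABC WT list held 89.45% of replicated ABC DKO peaks, 54.21% of ABC-only and 76.99% of FoB-only peaks. These were 0.0%, 0.0% and 80.56% with the reciprocal overlap, 63.18%, 14.59% and 66.45% with the same number of peaks, 91.06%, 57.99% and 79.23% with 200 bp windows, 88.53%, 51.18% and 77.91% with both windows and reciprocal overlap, and 64.25%, 14.71% and 68.92% with windows and the same number of peaks. ABC-only peaks near genes higher in ABC had an odds ratio of 1.12 (Fisher's exact p = 0.314) with the reciprocal overlap, which leaves 92246 of 92247 peaks as ABC-only and so tests all ABC DKO peaks. FoB-only peaks near these genes had 1.049 within 100 kb (Fisher's exact p = 0.824) and, with nearly all peaks counted as FoB-only, 1.094 with the reciprocal overlap (p = 0.538), against 0.829. FoB-only peaks near lower genes had 1.361 within 100 kb (Fisher's exact p = 0.472) and 1.618 with the reciprocal overlap (Fisher's exact p = 0.0973), against 1.735. The cause of the changes other than the reciprocal overlap was not tested.

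Of named genes called, 11 of 94, 51 of 86 and 39 of 90 in the 3 comparisons kept direction and call under every alternative run, and of called lists 0 of 4, 2 of 12 and 0 of 8. At 14.25 to 31.51 M reads the self-test recovered 0%, 3% and 9% of 1.5-fold changes. It changed only 67 genes by that fold, far fewer than were called in the data, which makes the adjusted threshold harder to pass. These shares therefore do not give the share detectable in the data. There, 1424 of 2432, 814 of 1026 and 701 of 1156 calls had a log2 fold change of at least 1, and the others were smaller.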

Other observations

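The tests of explanations were chosen only after the result was seen, although the ABC WT shares, the lists of the same length and quantile normalization that some of them use had been planned. FoB DKO libraries held more Aicda, Iigp1 and Gbp7 RNA and less Vpreb3 and Pax5 RNA than FoB WT, and ABC DKO held more Tbx21, Zeb2, Itgax and Zbtb32 RNA than FoB DKO. Iigp1 and Gdpd3 were also higher in ABC DKO than in ABC WT, Gdpd3 lying 16.54 Mb from Swap70.

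Of the authors' own calls at an FDR under 0.05, 3209, 1382 and 1353 for the comparisons in the order of the report, 2393, 1018 and 1134 were called here in the same direction. The splits of the 6 DKO libraries into 3 and 3 number 10, too few for a share under 0.05. Some of them, unlike the real split, put FoB DKO and ABC DKO libraries of the same number, which correlated, on the same side. Only the real split gave 1026 genes, and the highest of the others called 1.

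Myeloid markers were lower in ABC DKO than in ABC WT. The scaling of libraries was argued against, since the 15 abundant members kept a median of -3.95 (-3.954) after quantile normalization, with an SD of 0.866 between members. RNA of macrophages in the sorted ABC WT samples was not tested apart from the pattern itself, in which 15 of these 15 members were lower, and the B identity median of 0.148 lay within the SD of its members (0.243). In FoB DKO, 14 of the 15 were raised in replicate 1 over the other libraries of the same genotype. Erythroid markers (7 of 7, median -3.941), Klrk1, Gzma and Cd4 were lower as well, so other cells may have left RNA too, which was not tested. Dendritic markers went both ways, with 1 of 4 called higher and 2 lower. The B220+CD19+ gate is meant to remove macrophages. FoB DKO replicate 1 passed that gate too, but had a myeloid mean of 3.95 log2 CPM against -0.45 and -0.48 in replicates 2 and 3. Such a gate thus does not exclude RNA of these genes. Apoe of the 17 markers was abundant in FoB WT too (8.26 and 8.33 log2 CPM), while Vcam1 (10.81) and Csf1r (10.28) were among the most abundant in ABC WT. RNA of macrophages and changed expression by ABC themselves cannot be told apart, because either would give the median of -4.052 and bulk RNA does not show its cell of origin.

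Genes near Def6 and Swap70 changed in both cell types more often than others. DNA of another strain carried along with the deleted loci may contribute, since the odds ratio within 10 Mb was 4.012. Genes there were not called more often between ABC DKO and FoB DKO. Both carry the same deleted loci and lack the same proteins, so this cannot tell such DNA from loss of the proteins. For Gdpd3 a part of such DNA stays open, as genes between 10 and 20 Mb away had an odds ratio of 2.032 (Fisher's exact p = 0.0938). RNA of other cells may add Hbb-bs and Lst1 to the near genes, and without both the odds ratio was 3.663. Reads moved from Hmga1 to Hmga1-rs1 could explain that pair, with a gain of 64.4% of the CPM lost in FoB and 69.5% in ABC. Loss of the proteins acting on these genes cannot be told apart, because every DKO library carries both the loss and the deleted loci. Farther away 160 genes changed the same way in both, where independent lists would share 110.9.

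FoB-only peaks outnumbered ABC-only peaks by 6.09 to 1. Peak calling with another fragment length in the ABC DKO lists is a candidate cause, since the ABC WT list, called with the length of the FoB lists, held 76.99% of FoB-only peaks. A difference between the cell types cannot be told apart from it, as the ABC WT list held 54.21% of ABC-only peaks and no ABC DKO list with the shorter length was analysed. The ratio was 1.09 with lists of the same length and 3.89 with the first part of each list, both by a line order not documented as a strength in the DKO lists, and 6.24 with 200 bp windows. The ABC DKO lists also had higher tag thresholds (23 and 26, against 14 and 15 in FoB DKO and 13 in ABC WT). Their minimum distance between peaks was 324 bp against 112 bp. Windows of 200 bp even out the peak width but neither of these settings, whose part was not tested.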
